A study of Mus musculus with 57 samples.

How the data were processed

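RNA was sequenced from mouse salivary tissue in 57 samples. Of these, 24 were freshly dissected glands from embryonic day 13 (E13) to E18, with 4 samples at each stage. A further 11 were separated end bud epithelia kept for 4 h with neuregulin 1 (NRG1, a ligand of the receptor ERBB3) or without it, 8 were epithelia labelled E13 plus 72 h that received TORIN1 (an inhibitor of the kinase mTOR) or its vehicle DMSO, 8 were E16 glands labelled wild type or Erbb3 knockout (KO), and 6 were E13 epithelia cultured with NRG1 for 2, 3 or 4 days. The input was total RNA, per the labels, and libraries were made with a NEBNext Ultra kit, per the labels' protocols. Whether poly(A) RNA was selected is not given in the sources used here.

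The authors deposited 5 tables of raw counts per gene, 1 for each of these sets. Per the submitters' processing notes, the tools were fastp, STAR and featureCounts, with the genome build mm10. Their versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of near-identical gene copies, overlapping genes and antisense partners are uncertain. The Dcpp, haemoglobin and Hspa1 genes on the lists used here are such copies. The tables of glands, end buds and TORIN1 samples name genes by Ensembl identifier and the other 2 by symbol. Identifiers were given symbols and coordinates from GENCODE M21 on GRCm38. A match was found for 97.8% of the 35275 genes of the gland and end bud tables, holding 99.9% of their counts, and for 99.8% of the 54532 genes of the TORIN1 table.

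The culture table holds 5179 genes. How they were chosen is not given in the sources used here, so the share of them that changed says nothing about all genes. In 8 of its entries the symbol had been turned into a date. These entries, with 0.123% of the counts, were left out of library sizes and tests. Total counts in that table are sums over part of a library and are not depths. Total counts per sample were 13033868 to 25935489 in the gland table, 16027377 to 26306020 in the end bud table, 16318997 to 19671988 in the TORIN1 table and 8913271 to 11890488 in the KO table.

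Samples were grouped by their titles. The end bud samples titled E14 carry a stage label of E13 plus 4 h, and 1 of them (NRG1 C) a label of E13 plus 72 h, so the title decided their group and the words E13 and E14 stand for the titles. End bud columns marked S were read as NRG1 and those marked C as control. Nothing states that replicates came from separate litters or cultures, so p-values measure the spread between these samples, which may be technical in part. No pair of replicates had counts that agreed within sampling noise. The lowest chi-square per gene between replicates was 3.35. The highest were 161 to 219, between E18 D and the other E18 samples, which gave 9.92 to 17.7 among themselves.

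Counts were tested with edgeR 4.0.16 in R 4.3.3, using its robust quasi-likelihood F test, TMM normalization and its default filter on low counts. All groups of a table entered 1 fit, so that they share an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each log2 fold change is given with its standard error (SE), taken as its size divided by the square root of F. Levels are CPM, given as mean ± SD. They were computed over each sample's counts of tested genes multiplied by its TMM factor. A factor below 1 raises the levels. It was 0.701 in E18 D and 0.864 to 0.894 in the other E18 samples. On simulated counts with 200 changed genes, the KO design was fitted to 14758 genes. It recovered 10.6%, 56.1% and 92.2% of genes changed by a factor of 1.5, 2 and 4. The TORIN1 design recovered 15.2%, 52.4% and 93.8%, in a fit of 14761 genes. Unchanged genes made up 5.50% of the simulated calls for KO and 7.21% for TORIN1. Over all comparisons that share ran from 2.19% (E16 to E17) to 9.79% (culture day 2 to 3). The simulated genes varied independently, and no simulated sample stood apart as a whole. In the real data far more genes were called in most comparisons, so these rates need not hold there.

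A set of 25 gene lists was fixed before the data were examined. They cover acinar products, secretory machinery of the endoplasmic reticulum (ER) and Golgi, end bud progenitor genes, ERK feedback genes, the ERBB pathway, basal duct, luminal duct, myoepithelial and general epithelial genes, basement membrane, cell cycle, sterol and lipid synthesis, ATF4 and amino acid genes, FOXO targets, lysosome and autophagy, ribosome biogenesis, hypoxia and glycolysis, heat shock, and markers of neurons, Schwann cells, mesenchyme, endothelium, macrophages, erythroid cells and skeletal muscle. Some genes stand on 2 lists, for example Etv5, Dusp6 and Spry2 on the progenitor and ERK feedback lists. For each list the called members were counted over all genes tested and adjusted over the list alone, and the list was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison. The camera test with an estimated correlation and fry were alternatives. Overlaps of called genes between 9 pairs of comparisons without a shared library used a one-sided Fisher's exact test, 36 tests adjusted together.

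Genes were named by a rule fixed before the data were examined. It took Erbb3, Erbb2, Egfr, Nrg1 and Aqp5 always, then the 10 called genes with the highest and the 10 with the lowest fold change (5 each for day steps and for the difference between stages) among those with a mean log2 CPM of at least 1 and no overlap between the compared groups, and up to 4 members of each list by adjusted p. Unnamed gene models were left out. The text names part of the genes this rule took, picked after their values were seen. The result of 1 gene is not reported here. Genes with counts at or near 0 in a group are given by level, not by fitted fold change.

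Alternatives fixed before the data were examined were the size factors of DESeq2 1.42.0 in place of TMM, no filter and a stricter filter of 1 CPM, DESeq2 in place of edgeR, an added minimum log2 fold change of 1, fits of only the compared groups, a block for the replicate letter or number, and leaving out each sample in turn. Further alternatives were added after seeing the data. For the KO comparison they were a covariate for Xist class (above or below 100 counts), a covariate for the balance of general epithelial and mesenchyme genes, and fits of replicates 1 and 2 or 3 and 4 alone. For TORIN1 the samples TORIN1 A and DMSO D were left aside, and for the glands E18 D and E13 B. The values reported are those of the design fixed beforehand.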

Results

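Gene expression in the embryonic mouse salivary gland was profiled by RNA sequencing in 57 samples that fall into 5 sets. The sets followed whole glands through development, epithelium exposed to NRG1 for hours or days, epithelium under the mTOR inhibitor TORIN1, and glands labelled as knockout (KO) or wild type for the NRG1 receptor gene Erbb3. Glands from E13 to E18 had 4 samples per stage with total counts of 13033868 to 25935489. End buds, the epithelial tips that later form acini, had 3 control and 3 NRG1 samples titled E13 and 2 control and 3 NRG1 samples titled E14, with total counts of 16027377 to 26306020. The TORIN1 and DMSO groups had 4 samples each with total counts of 16318997 to 19671988, and the KO and wild-type groups 4 each with 8913271 to 11890488. The culture set had 2 samples at each of days 2, 3 and 4. Adjusted p-values are from edgeR's quasi-likelihood test, errors of log2 fold changes are SE, and errors of levels are SD.

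The first question was how gland transcripts change from E13 to E18. Genes of secretory products rose from traces to the most abundant transcripts. Smgc, which encodes a submandibular gland mucin-like protein (ENSMUSG00000047295, chromosome 15, 91838265 to 91861438 on GRCm38), had 2.21 ± 4.32 CPM at E13 and 78098 ± 4744 at E18 (n = 4 each). Bpifa2, a salivary secretory protein, went from 0.646 ± 1.26 to 73667 ± 3190 CPM. Prol1 had no counts in the 4 E13 samples and 9320 ± 523 CPM at E18, and Pip went from 0.217 ± 0.434 to 3103 ± 761 CPM. The traces of Smgc and Pip at E13 came from the sample E13 B, with 8.69 and 0.869 CPM. Aqp5, the water channel of acinar cells (ENSMUSG00000044217, chromosome 15, 99590782 to 99594829), rose from 1.16 ± 0.499 to 591 ± 150 CPM, a log2 change of 9.01 ± 0.29 (adjusted p = 8.41e-18). Of 25 measured acinar product genes 24 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 2.44e-35, and 7.85e-05 with an estimated correlation). The peroxidase gene Lpo rose by 10.50 ± 0.25 on the log2 scale.

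Other epithelial and immune groups rose as well. All 16 luminal duct genes rose, among them the keratin gene Krt7 (4.92 ± 0.19), and 13 of 14 general epithelial genes rose while 1 fell. Of 10 myoepithelial genes 8 rose and 2 fell, and the contractile gene Cnn1 rose by 6.80 ± 0.23. All 12 macrophage genes rose, with Lyz2 at 2.87 ± 0.17 and C1qc at 2.72 ± 0.18. Counts adjusted over the list alone were the same for these 4 lists, and their camera adjusted p with an estimated correlation was 7.85e-05 for the luminal duct and 0.00388 for each of the others. Of 36 ER and Golgi secretory genes 24 rose and 8 fell (adjusted p = 0.0016, and 0.183 with an estimated correlation). Of 25 lysosome and autophagy genes 19 rose and 3 fell (0.0203, and adjusted p = 0.214 with an estimated correlation).

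Progenitor, mesenchyme and neuronal genes moved the other way. The chromatin gene Hmga2, abundant in embryonic tissue, fell by 6.43 on the log2 scale and the embryonic globin gene Hbb-y by 7.47. The cartilage collagen gene Col2a1 fell from 259 ± 9.18 to 0.685 ± 0.396 CPM. Of 20 ribosome biogenesis genes 18 fell (adjusted p = 4.67e-05, and 0.0785 with an estimated correlation), among them Rrp12 (-1.63 ± 0.09) and Dkc1 (-1.58 ± 0.11). Of 15 neuronal genes 14 fell and 1 rose (adjusted p = 0.000172, and 0.183 with an estimated correlation), including Vip (-3.21 ± 0.26), a neuropeptide gene of parasympathetic neurons. Of 14 mesenchyme genes 10 fell and 2 rose (adjusted p = 0.0016, and 0.214 with an estimated correlation), with 11 lower adjusted over the list alone, including Fgf10 (-2.50 ± 0.14), Pdgfra (-2.25 ± 0.14) and Twist1 (-2.47 ± 0.15). Of 16 end bud progenitor genes 9 fell and 3 rose (adjusted p = 0.0363, and 0.29 with an estimated correlation), with Etv5 at -2.18 ± 0.07 and Bmp7 at -1.62 ± 0.09. Of 27 cell cycle genes 17 fell and 4 rose (adjusted p = 0.0315, and 0.326 with an estimated correlation).

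The receptor genes moved little by comparison. Erbb3 (ENSMUSG00000018166, chromosome 10, 128567523 to 128589652) had 112 ± 4.27 CPM at E13 and 147 ± 42.4 at E18, a log2 change of 0.40 ± 0.13 (adjusted p = 0.0112). That call was lost in the fit of only E13 and E18 and in a leave-one-out fit, and the sample E18 D had 85.2 CPM against 154 to 177 in the other E18 samples. Erbb2 rose by 0.53 ± 0.07 (adjusted p = 4.1e-07). Egfr (-0.07 ± 0.11, adjusted p = 0.569) and Nrg1 (-0.16 ± 0.14, adjusted p = 0.323) did not pass. The other lists gave no call as groups. Their camera adjusted p was 0.523 for ERK feedback, 0.325 for sterol and lipid synthesis, 0.683 for ATF4 and amino acid genes, 0.528 for FOXO targets, 0.452 for hypoxia and glycolysis, 0.0891 for heat shock, 0.681 for Schwann cells, 0.0926 for endothelium and 0.973 for skeletal muscle. It was 0.62 for the ERBB pathway, basal duct, basement membrane and erythroid lists. Median and mean differed in sign for the ERBB pathway (-0.07 and 0.11), basal duct (0.33 and -0.06), ATF4 (-0.03 and 0.10) and FOXO (-0.26 and 0.13) lists, all with an upward test, and the Schwann cell (0.08 and 0.09) and skeletal muscle (1.88 and 0.76) lists had a downward test. Across the 6 stages 13625 of 16521 genes were called, and between E13 and E18 6030 were higher and 5980 lower at E18.

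**Figure D1:**
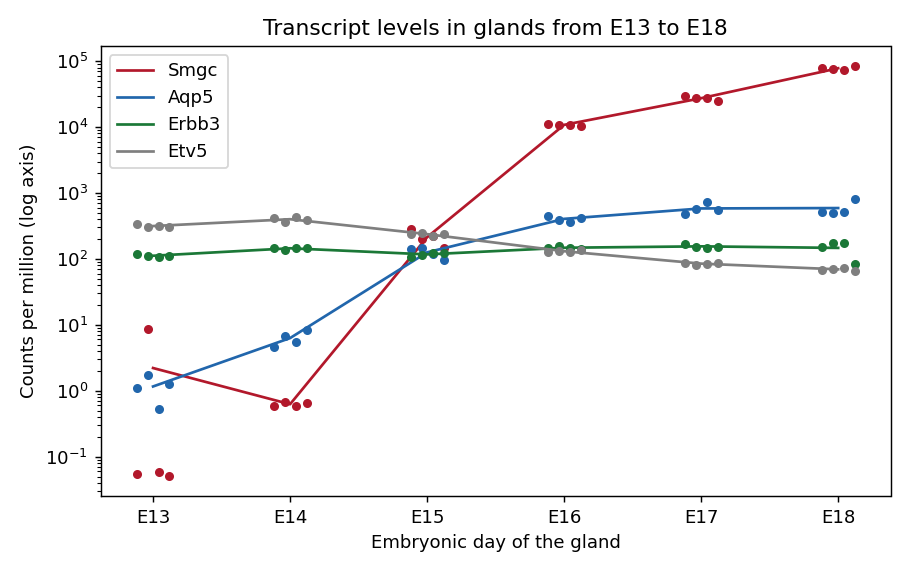
CPM (log axis) of Smgc, Aqp5, Erbb3 and Etv5 in glands from E13 to E18, with 1 point per sample (4 per stage) and a line through the stage means. Smgc rose from 2.21 to 78098 CPM and Aqp5 from 1.16 to 591 CPM between E13 and E18.

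Acinar genes were followed from day to day. From E13 to E14, 12 of 25 acinar genes rose (camera adjusted p = 2.99e-05, and 0.177 with an estimated correlation), and so did the general epithelial genes (12 of 14, adjusted p = 4.18e-12, and 0.00365 with an estimated correlation), for example the splicing factor gene Esrp1 by 0.85 ± 0.08. In the same step 22 of 27 cell cycle genes rose, or 26 adjusted over the list alone (adjusted p = 9.71e-11, and 0.00788 with an estimated correlation), Mki67 by 1.06 ± 0.14, and Aqp5 rose by 2.46 ± 0.27. From E14 to E15, 18 of 25 acinar genes rose and 1 fell (adjusted p = 7.14e-17, and 0.00851 with an estimated correlation). Smgc went from 0.625 ± 0.047 to 213 ± 57.1 CPM, Aqp5 rose by 4.31 ± 0.22 and Bhlha15, a transcription factor gene of secretory cells, by 3.94 ± 0.18. From E15 to E16, 21 acinar genes rose (adjusted p = 1.93e-50, and 1.58e-05 with an estimated correlation), as did 23 of 36 ER and Golgi genes (adjusted p = 4.34e-11, and 0.00617 with an estimated correlation). Pip rose from 0.812 ± 0.288 to 100.2 ± 11.3 CPM, Xbp1, a regulator of secretory capacity, by 1.18 ± 0.09 and Aqp5 by 1.69 ± 0.19. From E16 to E17, 9 acinar genes rose (adjusted p = 5.06e-33, and 0.000299 with an estimated correlation), and 8 ER and Golgi genes. Adjusted over the list alone, 13, 19, 23, 14 and 14 acinar genes were higher at the steps in order, and 1, 1, 1, 0 and 1 lower. From E17 to E18, 11 acinar genes rose and 1 fell (adjusted p = 1.78e-19, and 0.00312 with an estimated correlation), while 25 of 27 cell cycle genes fell (adjusted p = 4.45e-40, and 1.34e-05 with an estimated correlation).

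The number of genes that changed was highest from E14 to E15, with 4082 higher and 4123 lower. It was 1953 higher and 1261 lower from E13 to E14, 2017 and 1866 from E15 to E16, 560 and 348 from E16 to E17, and 976 and 1171 from E17 to E18. In fits of only the compared stages, the step from E13 to E14 called 5221 genes, that from E16 to E17 called 1804 and that from E17 to E18 called 647. The order of the steps below the highest thus depended on which stages shared the fit. Leaving out E16 B, E16 C, E16 D or E17 B left 523, 523, 536 and 580 calls from E16 to E17.

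The next question was what NRG1 does to end bud epithelium within 4 h. In end buds titled E13, genes of ERK signalling rose. Etv5 went from 5.33 ± 1.98 to 458 ± 25.1 CPM (log2 change 6.38 ± 0.56, n = 3 each, adjusted p = 5.86e-05), the ERK phosphatase gene Dusp6 rose by 5.50 ± 0.47, and the immediate early genes Egr2 and Egr1 rose by 4.14 ± 0.13 and 3.40 ± 0.09. Of 26 ERK feedback genes 19 rose and 2 fell (camera adjusted p = 1.1e-22, and 0.0379 with an estimated correlation). Of 16 end bud progenitor genes, which include Etv5 and Dusp6, 12 rose and 1 fell (adjusted p = 4.53e-14, and 0.007 with an estimated correlation), with Ccnd1 at 3.35 ± 0.18 and Spry2 at 2.51 ± 0.16.

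Biosynthetic genes rose together. All 24 sterol and lipid synthesis genes rose (adjusted p = 4.29e-33, and 0.007 with an estimated correlation), with Msmo1 at 2.75 ± 0.12, Idi1 at 1.76 ± 0.10 and the squalene epoxidase gene Sqle at 1.56 ± 0.07. Of 20 ATF4 and amino acid genes 19 rose and 1 fell (adjusted p = 3.43e-42, and 0.00399 with an estimated correlation), including Chac1 (5.04 ± 0.24), the arginine transporter gene Slc7a1 (2.92 ± 0.09) and the glycyl-tRNA synthetase gene Gars (1.53 ± 0.07). Of 20 ribosome biogenesis genes 18 rose (adjusted p = 6.49e-27, and 0.019 with an estimated correlation), with Rrp12 at 2.67 ± 0.13 and Nop56 at 1.48 ± 0.09. Of 15 FOXO targets 13 fell and none rose (adjusted p = 6.73e-13, and 0.00399 with an estimated correlation), including Klhl24 (-1.31 ± 0.07), the cell cycle inhibitor gene Cdkn1b (-1.04 ± 0.07) and Ccng2 (-0.98 ± 0.07). Counts adjusted over the list alone were the same for these 4 lists and for both lists before them. Of 27 cell cycle genes 13 rose and 1 fell (adjusted p = 2.3e-05, and 0.161 with an estimated correlation).

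Acinar genes split. Aqp5 rose from 0.609 ± 0.354 to 2.96 ± 0.924 CPM (2.24 ± 0.35, adjusted p = 0.000208), the potassium channel gene Kcnn4 by 4.05 ± 0.30 and the ion cotransporter gene Slc12a2 by 2.91 ± 0.11. In all 7 of 21 acinar genes rose and 4 fell, or 6 lower adjusted over the list alone. The list median was -0.04 and its mean 0.49, and the camera test gave up (adjusted p = 0.0435, and 0.133 with an estimated correlation). Erbb3 fell by 0.37 on the log2 scale (SE 0.07, adjusted p = 0.000946) and Egfr by 0.80 (SE 0.09), while Erbb2 (-0.11 ± 0.06, adjusted p = 0.183) and Nrg1 (0.232 ± 0.0741 CPM in controls and 0.481 ± 0.135 with NRG1, adjusted p = 0.124) did not pass. The keratin genes Krt15 (-1.75 ± 0.24) and Krt19 (-1.60 ± 0.24), the growth factor pathway gene Smad9 (-3.92 ± 0.63), the pyruvate dehydrogenase kinase gene Pdk4 (-3.54 ± 0.56) and Fam107a (-3.81 ± 0.20) fell. In total 3740 of 16180 genes were higher and 3127 lower with NRG1.

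In end buds titled E14 the direction was largely the same. Of the 3731 genes higher and 3112 lower at E13 among those tested at both titles, 2484 were also higher and 1830 also lower at E14, against 757 and 499 for independent lists. The correlation of log2 fold changes across 16075 genes, which are not independent replicates, was 0.627 (Pearson) and 0.671 (Spearman). Etv5 rose by 3.17 ± 0.54, Dusp6 by 2.44 ± 0.45 (lost in the fit of only the compared groups), Egr1 by 2.31 ± 0.10, Slc7a1 by 1.90 ± 0.10, Msmo1 by 2.48 ± 0.13 and Adm2 by 3.48 ± 0.26 (n = 3 NRG1 and 2 control). Aqp5 rose by 1.88 ± 0.28, while Erbb3 fell by 0.78 (SE 0.08), Egfr by 0.69 (SE 0.10), Erbb2 by 0.34 (SE 0.07), Klhl24 by 1.10, Krt15 by 1.54 and Fam107a by 2.91. Nrg1 itself was called higher (1.15 ± 0.39, adjusted p = 0.0319), a call lost in a leave-one-out fit, with the replicate block and in the fit of only the compared groups.

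Among the lists at E14, 22 of 24 sterol genes, 18 of 20 ATF4 genes and 18 of 20 ribosome biogenesis genes rose, and 13 of 15 FOXO targets fell. With an estimated correlation these held, at adjusted p = 0.0062, 0.00532, 0.0251 and 0.00516. ERK feedback (19 of 26 higher, 2 lower) and end bud progenitor genes (9 of 16 higher, 1 lower) were called with adjusted p = 3.61e-12 and 8.21e-05, and had adjusted p = 0.13 and 0.126 with an estimated correlation. Adjusted over the list alone, 23 sterol, 20 ERK feedback and 10 progenitor genes were higher. In total 3271 genes were higher and 2593 lower with NRG1 at E14, and with both titles in 1 fit 4262 were higher and 3799 lower.

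The effect differed between the 2 titles for 367 genes, of which 119 had a higher and 248 a lower fold change at E14. The progenitor list was lower in this difference, with 6 of 16 genes called lower, or 10 adjusted over the list alone (adjusted p = 6.09e-15, and 0.0235 with an estimated correlation). Chac1 rose from 0.740 ± 0.170 to 24.7 ± 4.78 CPM at E13 and went from 5.06 ± 1.49 to 21.7 ± 3.74 at E14, a difference of -2.93 ± 0.34 (adjusted p = 0.000916). Pfkfb3, a regulator of glycolysis, differed by -2.07 ± 0.32, and Ackr3 and Edn2 by 2.54 ± 0.35 and 2.04 ± 0.31. The difference for Erbb3 (-0.40 ± 0.11, adjusted p = 0.0789) and Aqp5 (-0.35 ± 0.44, adjusted p = 0.764) did not pass. The count of 367 was 234 and 229 without E13 control A or B, 240, 140 and 176 without E13 NRG1 A, B or C, 1084 without E14 control B and 167 without E14 NRG1 B. Without E14 control B a lone control remained, which was assumed to vary like the other groups.

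The 2 control groups also differed in their tissue markers. From E13 to E14 controls, 10 of 10 endothelial genes rose (Cdh5 by 4.42 ± 0.53, Cldn5 by 4.37 ± 0.45), 12 of 14 mesenchyme genes (Fgf10 by 4.19 ± 0.77) and 6 of 9 erythroid genes (Hbb-bs by 5.12 ± 0.67). With an estimated correlation the adjusted p was 0.077, 0.281 and 0.216. ERK feedback genes were higher in E14 controls too, 22 of 26 (adjusted p = 6.76e-16, and 0.12 with an estimated correlation). Aqp5 rose by 3.52 ± 0.35 and the basal keratin gene Krt5 fell by 1.77 (SE 0.30). The calls of Krt5 and Fgf10 were lost in the fit of only these groups. The mesenchyme gene Col1a1 had 38.5 to 116 CPM in E13 controls and 320 and 1165 CPM in E14 controls. Of 16180 genes 2329 were higher and 1488 lower in E14 controls, and 2065 were called in the fit of only these groups.

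TORIN1, which inhibits both mTOR complexes, was compared with DMSO in epithelium at 72 h. Most lipid synthesis genes and some secretory genes fell. Of 24 sterol and lipid synthesis genes 19 fell, or 23 adjusted over the list alone (camera adjusted p = 1.45e-35, and 0.111 with an estimated correlation), with the desaturase gene Scd1 at -2.11 ± 0.27 (n = 4 each, adjusted p = 0.00565) and Hmgcs1 at -1.02 ± 0.14. Smgc fell from 42830 ± 8322 to 14722 ± 6093 CPM (-1.54 ± 0.31, adjusted p = 0.027), and Mucl2 (-4.56 ± 0.56) and Scgb2b27 (-4.52 ± 0.43) fell as well. The carbonic anhydrase gene Car6 fell from 3.56 ± 2.58 to 0.235 ± 0.215 CPM. Of 24 acinar genes 7 fell and 1 rose, or 10 and 2 adjusted over the list alone (adjusted p = 0.00487, and 0.548 with an estimated correlation). Aqp5 had 364 ± 45.5 CPM with DMSO and 266 ± 108 with TORIN1 (-0.45 ± 0.25, adjusted p = 0.313), which did not pass.

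Smaller groups of genes changed on other lists. Of 20 ATF4 and amino acid genes 7 fell (10 lower and 1 higher adjusted over the list alone), including the asparagine synthetase gene Asns (-1.49 ± 0.12) and Chac1 (-2.01 ± 0.24), with adjusted p = 3.31e-08, and 0.177 with an estimated correlation. Of 27 cell cycle genes 8 fell, or 15 adjusted over the list alone, with Ccnb2 at -0.73 ± 0.12, and of 36 ER and Golgi genes 7 fell, or 10, with Xbp1 at -0.74 ± 0.15. Both had adjusted p = 0.338 with an estimated correlation. Rising genes included Ano7 (3.67 ± 0.39), the transcription factor gene Pou2f3 (2.79 ± 0.27), the basement membrane collagen gene Col4a2 (0.65 ± 0.10, 1 of 6 called of 15 on its list, or 7 adjusted over the list alone) and the receptor gene Kit (0.89 ± 0.15, 1 of 6 called of 16 end bud progenitor genes, or 9). With an estimated correlation these 2 lists had adjusted p = 0.338 and 0.0998. Of 10 macrophage genes only Mrc1 was called (-2.11 ± 0.51), with 8 lower adjusted over the list alone, a list median of -1.30 and adjusted p = 0.338 with an estimated correlation. Ribosome biogenesis genes had 1 of 20 called, higher (list adjusted p = 0.0204, and 0.674 with an estimated correlation).

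Erbb3 (-0.09 ± 0.16, adjusted p = 0.778), Erbb2 (0.19 ± 0.09, adjusted p = 0.216), Egfr (0.01 ± 0.25, adjusted p = 0.984) and Nrg1 (0.36 ± 0.33, adjusted p = 0.572) did not pass with TORIN1. In total 369 of 14985 genes were higher and 504 lower, 873 together. The sample TORIN1 A stood apart from the others, and the count was 3856 without it, 144, 205, 151 and 567 without DMSO A, B, C or D, and 261 and 255 without TORIN1 C or D. It was 4845 without both TORIN1 A and DMSO D, a setting chosen after the data were seen in which Aqp5 was called lower (-0.83), and 1805 with DESeq2. The calls of Smgc, Car6, Kit, Ccnb2, Xbp1 and Mrc1 were lost in a leave-one-out fit, each with its direction kept.

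In the Erbb3 KO set the targeted gene was examined first. Erbb3 had 89.7, 69.6, 124 and 118 CPM in wild-type samples 1 to 4 and 35.1, 32.0, 73.6 and 68.6 in KO samples 1 to 4. The 2 groups overlapped, since wild-type 2 lay below KO 3. The log2 change was -0.94 ± 0.29 (adjusted p = 0.0619), so the reduction of Erbb3 transcripts did not pass over all genes. It did in some other fits, among them DESeq2 (-0.93) and the replicate block. Each KO sample lay below the wild-type sample of the same number, but the numbers were not taken to pair the samples. KO and wild type are the labels' names, and each direction below rests on those labels. The part of the gene that was deleted is not given in the sources used here, and counts over a whole gene include transcripts that make no receptor.

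Secretory genes were lower in KO glands at E16. Smgc had 455 ± 289 CPM in wild type and 12.3 ± 11.7 in KO (-5.20 ± 1.06, n = 4 each, adjusted p = 0.0449), Bpifa2 had 247 ± 243 and 6.42 ± 3.34 CPM (-5.26 ± 0.87, adjusted p = 0.0354) and A2ml1 had 112 ± 136 and 2.72 ± 1.48 CPM (-5.33 ± 1.04, adjusted p = 0.0428). Lpo (-3.78 ± 0.65), Agr2 (-3.51 ± 0.52) and the secretory granule gene Rab3d (-1.19 ± 0.15) fell. Pip fell from 6.86 ± 7.26 to 0.197 ± 0.179 CPM, Slc44a4 from 8.82 ± 4.03 to 0.691 ± 0.442 and Slc12a2 from 101 ± 13.7 to 50.5 ± 14.8. Wild-type 1 stood above the other wild-type samples, with 609 CPM of Bpifa2 against 98.7 to 170.4 and 315 CPM of A2ml1 against 33.4 to 56.5. It thus raised the wild-type means of these genes. Its mitochondrial share was also higher, at 2.68% against 1.02 to 1.55% in the other wild-type samples. Of 22 acinar genes 11 fell and none rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 1.83e-12, and 0.397 with an estimated correlation). Aqp5 had 204 ± 57.9 CPM in wild type and 147 ± 38.0 in KO (-0.47 ± 0.22, adjusted p = 0.161), which did not pass. Smgc lay between 241 and 873 CPM in wild type and between 1.16 and 23.7 CPM in KO. In the E16 glands of the stage series, which stand in a separate table, it had 10543 to 11179 CPM. Of 9 erythroid genes the embryonic globin genes Hba-x (1.17 ± 0.30) and Hbb-y (1.06 ± 0.30) rose in KO (camera adjusted p = 0.132). Twist1 (1.11 ± 0.25) rose among 14 mesenchyme genes, of which 1 fell, and Fabp7 (0.94 ± 0.23) rose among 10 Schwann cell genes. Hba-x, Hbb-y, Twist1 and Fabp7 fell from E13 to E18 in the stage series. The balance of tissues varied within both genotypes: the epithelial gene Epcam had 592, 574, 371 and 422 CPM in wild-type samples 1 to 4 and 402, 357, 564 and 500 in KO samples 1 to 4, and Col1a1 had 3306, 4301, 5989 and 5817 against 6463, 5918, 3516 and 4566.

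**Figure D2:**
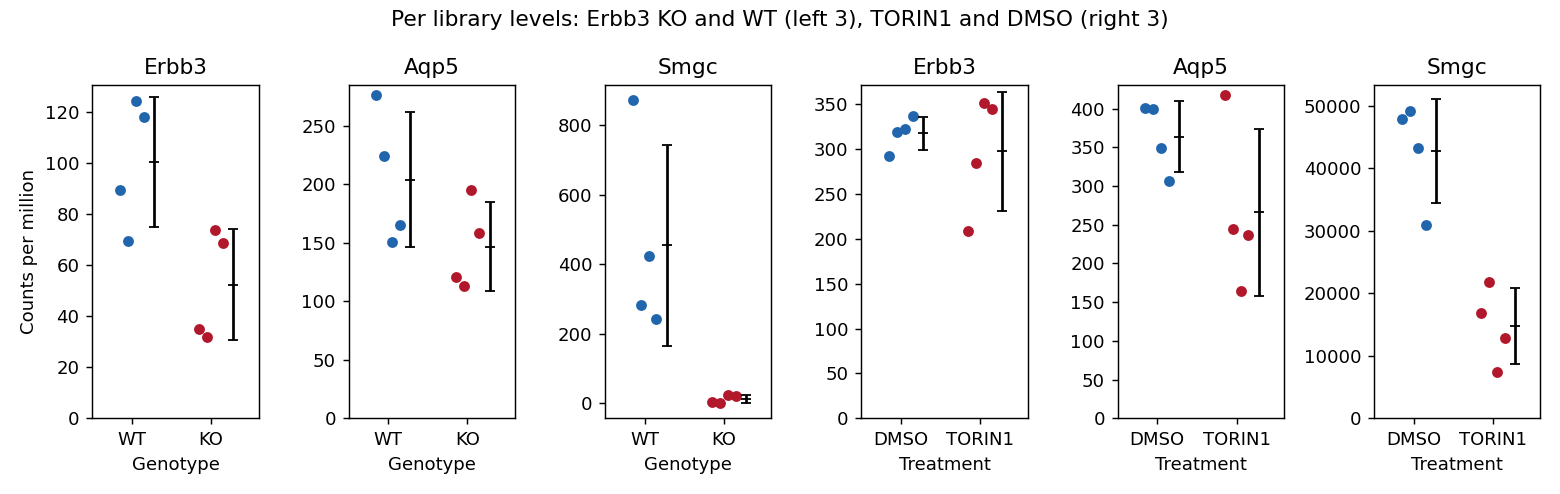
CPM of Erbb3, Aqp5 and Smgc in E16 wild-type and KO glands (left 3 panels) and in epithelium with DMSO or TORIN1 (right 3 panels), with 1 point per sample and the group mean ± SD beside them (n = 4 each). Smgc was at most 23.7 CPM in KO samples and at least 241 CPM in wild type, while the groups overlapped for Erbb3 and Aqp5 in both sets.

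Among other lists, 7 of 24 sterol genes fell in KO, or 10 adjusted over the list alone, with Idi1 at -1.30 ± 0.28 (adjusted p = 2.49e-05, and 0.397 with an estimated correlation). Of 15 luminal duct genes 4 fell, with Prom1 at -2.26 ± 0.34, and of 15 ERBB pathway genes 3 fell, with the ligand gene Egf at -1.86 ± 0.31. Of 9 basal duct genes 3 rose, namely Krt14 (0.65 ± 0.16), Krt17 (0.66 ± 0.18) and Wnt10a (0.83 ± 0.18). Adjusted over the list alone, 5 luminal duct genes were lower, 5 ERBB pathway genes lower and 1 higher, and 4 basal duct genes higher. These lists had adjusted p = 0.649, 0.397 and 0.397 with an estimated correlation. Of 12 macrophage genes 3 rose, among them the complement gene C1qa (0.89 ± 0.20), or 6 and 1 lower adjusted over the list alone (adjusted p = 0.016, and 0.46 with an estimated correlation). All 12 macrophage genes rose from E13 to E18 in the stage series. Among single genes Ush1c (2.61 ± 0.43) and the signalling inhibitor gene Socs1 (1.59 ± 0.28) rose. Lists that moved with NRG1 at 4 h also held called genes. Psph (0.81), Atf5 (0.70), Slc3a2 (0.65), Rrp9 (0.88), Ppan (0.63) and Etv4 (0.92), of the ATF4, ribosome biogenesis and ERK feedback lists, rose. Of the FOXO targets Irs2 (-1.13), Insr (-0.88) and Bcl6 (-0.83) fell and Ddit4 (1.13) rose, and the progenitor gene Kit (-0.58) fell. Except Ddit4 and Kit, they moved as their lists did with NRG1, while sterol genes went the other way. Other fits of these genes are not given. Egfr (-0.54 ± 0.20, adjusted p = 0.0918), Erbb2 (-0.22 ± 0.18, adjusted p = 0.408) and Nrg1 (-0.65 ± 0.30, adjusted p = 0.153) did not pass.

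In total 424 of 14991 genes were higher and 630 lower in KO, 1054 together. That count was 509, 3723, 24 and 81 without wild-type 1, 2, 3 or 4, and 5, 3, 333 and 136 without KO 1, 2, 3 or 4. It was 2626 with DESeq2, 2121 without a filter and 2348 with a covariate for Xist class, the last chosen after the data were seen. The calls of Smgc, Bpifa2, A2ml1, Lpo, Agr2, Pip, Rab3d, Slc12a2, Krt14, Krt17, Wnt10a, Idi1, Egf, Prom1, C1qa, Socs1, Ush1c, Hba-x, Hbb-y, Twist1 and Fabp7 were lost in a leave-one-out fit, each with its direction kept.

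**Figure D3:**
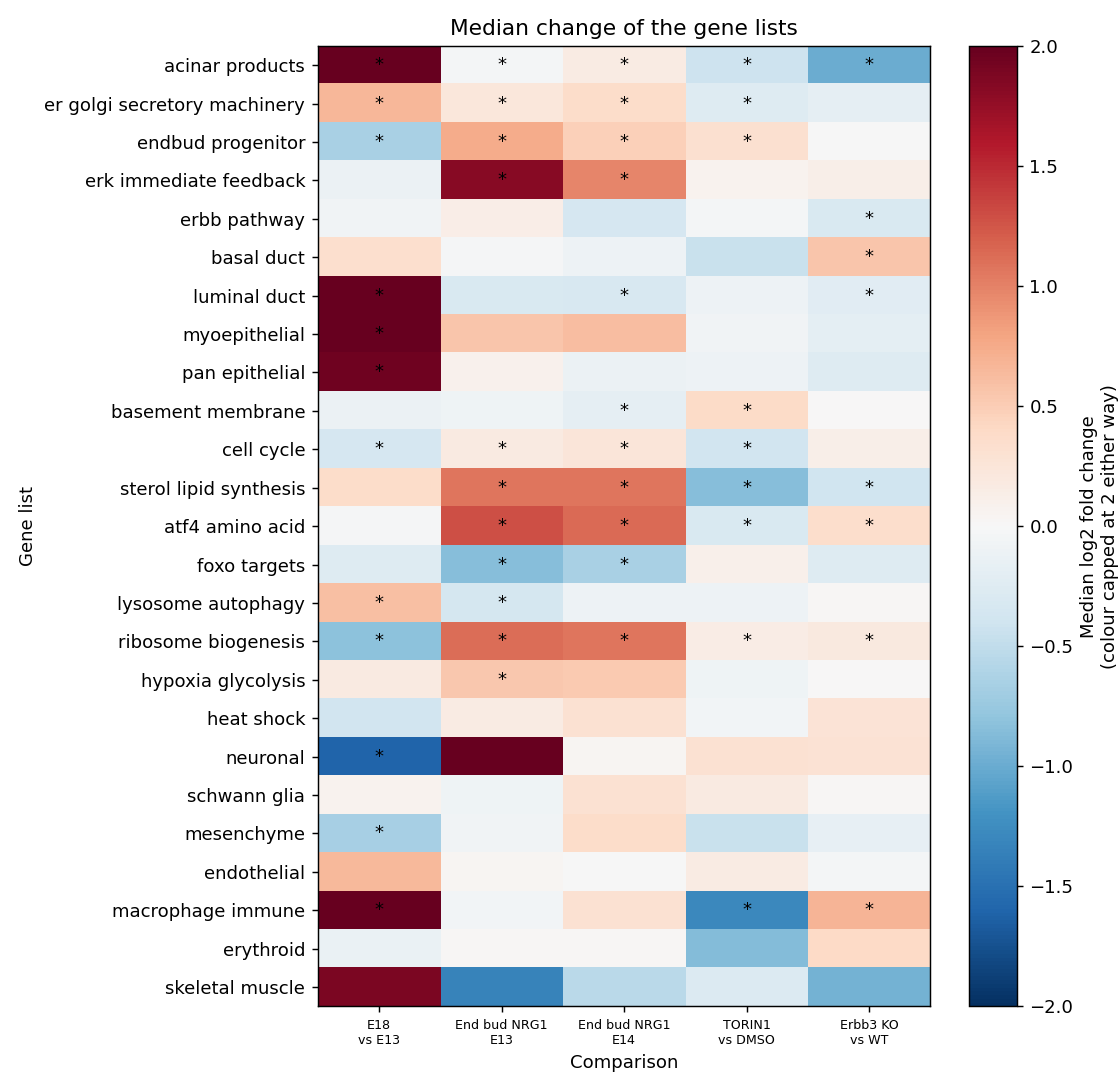
Median log2 fold change of the measured members of 25 gene lists (vertical axis) in 5 comparisons (horizontal axis), with colour capped at 2 either way. An asterisk marks an adjusted p under 0.05 in the camera test at a preset correlation. With an estimated correlation none of the TORIN1 or KO lists keeps its call.

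The last set followed E13 epithelium through days 2 to 4 of culture with NRG1. It holds no control without NRG1, so it compares days. Acinar genes rose from day 2 to day 4, with Bpifa2 at 6.77 ± 0.27, Pip at 4.77 ± 0.23, Smgc at 3.60 ± 0.11 and Aqp5 at 0.84 ± 0.06 (n = 2 each). Of the 19 acinar genes measured there 14 rose and 5 fell (camera adjusted p = 1.95e-06, and 0.778 with an estimated correlation), and all 5 basal duct genes rose, with Krt5 at 2.79 ± 0.18 (adjusted p = 0.0127, and 0.778 with an estimated correlation). The squamous keratin gene Krt13 rose by 5.63 ± 0.70. Of 11 basement membrane genes 7 fell and 2 rose, with Col4a2 at -1.40 ± 0.06 (adjusted p = 0.0092, and 0.778 with an estimated correlation). All 8 macrophage genes measured there rose too, with Mrc1 at 2.78 ± 0.69, Lyz2 at 2.27 ± 0.57 and C1qa at 1.83 ± 0.46, and so did 7 of 8 hypoxia and glycolysis genes, with Bnip3 at 1.49 ± 0.38. Neither list passed as a group (adjusted p = 0.151 for both). Sox10, a transcription factor gene of end buds, fell by 3.43 on the log2 scale, and Ano7 fell from 33.4 ± 0.451 to 0.0682 ± 0.0965 CPM of the counts in that table. Erbb3 (-0.31 ± 0.07) and Erbb2 (-0.22 ± 0.06) fell slightly. The calls of Erbb2, Mrc1, Lyz2, C1qa and Bnip3 were lost in a leave-one-out fit. Counts adjusted over the list alone were the same for these 5 lists.

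Of the 5171 genes tested in culture 2520 were higher and 2224 lower at day 4 than at day 2. The steps from day 2 to 3 and from day 3 to 4 gave 1239 higher and 1310 lower, and 1272 higher and 1138 lower. The table was not a sample of all genes, and with 2 samples per day a single sample weighed heavily. The first step called 122 and 450 genes without day 2 samples 1 and 2, numbered by column, and 1258 without day 3 sample 1, and the second called 1166 without day 3 sample 1 and 1155 without day 4 sample 2.

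Called genes overlapped between sets that share no library. These tests treat genes as independent, which genes that change together are not, so their p-values are too small. Whether an overlap has a shared cause was not tested. Of 619 genes lower in KO among those also tested in the glands, 363 were among the genes higher at E18 than at E13, against 226 for independent lists (one-sided Fisher's exact test, adjusted p = 1.32e-29). Of 619 lower in KO among those tested with TORIN1, 70 were lower with TORIN1, against 21.1 (adjusted p = 9.07e-19). Of 491 genes lower with TORIN1, 330 were higher at E18, against 184 (adjusted p = 1.69e-41). The NRG1 response at 4 h overlapped with E18 in the other direction, with 1783 of 3707 genes higher with NRG1 at E13 being lower at E18, against 1378 (adjusted p = 1.67e-54). Genes lower in KO were lower with NRG1 in 173 cases, against 121 (adjusted p = 2.81e-07), and genes higher in KO were higher with NRG1 in 150, against 107 (adjusted p = 3.34e-06). Genes higher at day 4 of culture were higher at E18 in 1672 of 2422 cases, against 1110. Genes lower with TORIN1 were higher at day 4 in 274 of 334 cases, against 162 (adjusted p = 1.61e-38), and those higher with TORIN1 were lower at day 4 in 195 of 220, against 95.0 (adjusted p = 2.85e-46). The correlation of log2 fold changes across 5008 genes in that last pair was -0.612 (Pearson) and -0.539 (Spearman). Most genes of the culture table were called between day 2 and day 4, and how its genes were chosen is not given. Overlaps with that set thus compare directions within a selected set of genes.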

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

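Tests chosen only after the result was seen were the permutation test of acinar against general epithelial genes in KO glands and the fits without E14 control C or E14 NRG1 C. The tissue balance covariate in KO and the fit without TORIN1 A and DMSO D were settings chosen after the data were seen.

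The acinar product genes were lower in KO than in wild-type glands, with 11 of 22 called. A lower share of epithelium in the KO samples would lower all epithelial genes alike if the mix of epithelial cells stayed the same. The mean log2 CPM of the 22 acinar genes minus that of the 14 general epithelial genes differed by -1.52 in KO, at -3.50 to -2.73 in the 4 KO and -1.82 to -1.30 in the 4 wild-type samples (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 samples can give). That p adds no independent support, since the acinar genes were known to be lower when the test was chosen. The general epithelial genes had a median log2 fold change of -0.255. The size of the difference argues against a lower share of epithelium as the whole cause, if the mix of epithelial cells stayed the same. All 11 stayed called and lower with a covariate for the balance of epithelial and mesenchyme genes, which argues against that balance as the whole cause. An effect of the genotype on acinar genes remains a hypothesis. Erbb3 itself overlapped between the genotypes and was called in some fits only, and the count of all calls depended on single samples. A different mix of epithelial cells and a difference in developmental age between the groups were not tested. Much of what changes with stage went the way of a younger age of the KO glands. Genes lower in KO overlapped with those higher at E18 beyond independent lists. Hba-x, Hbb-y, Twist1 and Fabp7, which fell with stage, were higher in KO. C1qa (0.89), C1qb (0.77) and C1qc (0.97), of the macrophage list that rose with stage, were also higher, which goes the other way. Smgc made up 0.0252 to 0.0912% of counts in wild-type samples. In the stage series it made up 0.0157 to 0.0304% at E15 and 1.06 to 1.13% at E16. A difference in age thus stays open as an explanation.

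The effect of NRG1 differed between end buds titled E14 and E13 for 367 genes by a test of the difference itself. Among them were Chac1 (-2.93), Pfkfb3 (-2.07), Ackr3 (2.54) and Edn2 (2.04), as log2 fold change at E14 minus that at E13. The sample E14 control C had less Col1a1 than the other E14 control, and E14 NRG1 C carried a stage label unlike the rest. The chi-square per gene of E14 NRG1 C was 11.1 against E14 NRG1 A and 6.90 against B, where A and B gave 11.5. Its counts thus did not stand apart from theirs. Without E14 control C, where the lone control left was assumed to vary like the other groups, 272 of the 367 genes were called again, and without E14 NRG1 C 248 were, so most of these calls did not need either sample. Stage and the tissue left on the end buds differ together between the titles and were not told apart, and the count ran from 140 without E13 NRG1 B to 1084 without E14 control B.

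Fold changes with TORIN1 ran opposite to those from day 2 to day 4 of culture, with a correlation of -0.612 across genes, which are not independent replicates. It was -0.624 without TORIN1 A and DMSO D, the samples that stood apart, which argues against those samples as the cause. Without the 10 most abundant genes of either table it was -0.611, which decides nothing, since only 12 of the 5008 genes were then left out. A delay of the changes that come with days of culture may underlie the pattern. These sets cannot test that hypothesis, since the TORIN1 and DMSO samples were all labelled 72 h. Whether the sets were cultured or sequenced together is not given in the sources used here. The genes of the culture table were selected in a way that is not given, so the size of the correlation does not extend to all genes.

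Some single samples lay far from the other 3 of their group. Of 58 groups of values 10 had such a sample. Chance gives about 1 in 20 groups, but that rate does not apply here as it stands, since the genes were partly picked after their values were seen and 4 of the 10 came from wild-type 1 and 3 from E13 B. Aqp5 had 815 CPM in E18 D and 505 to 523 in the other E18 samples. E18 D also stood apart as a whole, with a TMM factor of 0.701 against 0.864 to 0.894. Its mitochondrial share was 0.764% against 1.40 to 1.57%. It entered the spread that all stage comparisons share. The sample E13 B had 8.69 CPM of Smgc, 2.53 of Bpifa2 and 0.869 of Pip, where the other E13 samples had 0.0513 to 0.0590, 0 to 0.0513 and 0. Wild-type 1 of the KO set had 609 CPM of Bpifa2, 315 of A2ml1, 17.7 of Pip and 14.9 of Slc44a4, where the other wild-type samples had 98.7 to 170.4, 33.4 to 56.5, 2.02 to 4.39 and 6.63 to 7.08. The total count was 18965297 in TORIN1 A against 17168578 to 17384288 in the other TORIN1 samples, and 20221820 in E15 A against 17719493 to 17985536 in the other E15 samples.

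Other splits of the same samples into groups of the same sizes gave far fewer calls in most comparisons. Across the 6 stages the real grouping called 13625 genes and the highest other of 40 drawn splits 7. For pairs of stages, in fits of only the compared samples with 35 splits each, the real split called 10293 from E13 to E18, 5221 from E13 to E14, 8416 from E14 to E15, 4517 from E15 to E16 and 647 from E17 to E18, and the highest other split 0. From E16 to E17 it called 1804 against 2. The real split called 873 against 16 for TORIN1 and 1054 against 11 for KO. In each of these the real split alone gave as many genes, 1 of the splits. That share, 1 in 35 or 1 in 40, is the smallest these splits can give and was not adjusted over the comparisons. It argues against a chance split only weakly. Whether the samples came from separate litters or cultures is not given, so a shared origin of a group's samples was not excluded. For NRG1 over both titles it called 8061 against 5776 in 100 drawn splits, again 1 of them. The other splits were drawn within each title, and the highest kept the 3 E13 controls together, so it held the real contrast at E13. The end buds titled E13 allow 10 splits, too few for a share under 0.05, with 7498 genes for the real split and 0 for the highest other.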

How the results depend on the processing

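Settings chosen only after the data were seen were the Xist class and tissue balance covariates, replicates 1 and 2 or 3 and 4 alone in the KO set, and the fits without TORIN1 A and DMSO D or without E18 D and E13 B. The pairs of replicates were picked after Erbb3 was seen to differ between them, so their values stand here as limits only. The causes of the changes below were not tested, except that a stricter threshold lowers a count by construction. Samples outside a comparison can change its count only through what the fit shares, such as the estimate of the spread.

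With an absolute log2 fold change of at least 1, the counts were 6397 from E13 to E18, 837 from E13 to E14, 2098 from E14 to E15, 988 from E15 to E16, 227 from E16 to E17 and 397 from E17 to E18. They were 1419 and 876 for NRG1 at E13 and E14, 93 for the difference between them, 1171 for both titles, 1450 between controls, 260 for TORIN1 and 323 for KO, and in culture 450, 390 and 1052 from day 2 to 3, 3 to 4 and 2 to 4. Fits of only the compared groups called 5221 from E13 to E14, 1804 from E16 to E17, 647 from E17 to E18 and 2065 between controls. DESeq2 called 801 for the difference between titles, 1805 for TORIN1 and 2626 for KO, and KO without a filter gave 2121. Without E18 D and E13 B, neither of which belongs to that step, 1829 were called from E16 to E17. Without TORIN1 A and DMSO D 4845 were called, 870 of them among the 873. In KO the Xist covariate gave 2348 (1051 shared with the 1054), replicates 1 and 2 alone 33 (26 shared) and replicates 3 and 4 alone 5663 (971 shared).

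Leaving out each sample in turn gave 13391 to 14570 across stages, 11523 to 12136 from E13 to E18, 2474 to 3029, 6858 to 8037, 3188 to 3633, 523 to 743 and 1606 to 3109 for the day steps in order, 5720 to 6291 and 4053 to 6618 for NRG1 at E13 and E14, 140 to 1084 for their difference, 7389 to 8111 for both titles, 2866 to 3897 between controls, 144 to 3856 for TORIN1, 3 to 3723 for KO, and 122 to 2134, 1155 to 1957 and 3422 to 4323 for culture days 2 to 3, 3 to 4 and 2 to 4.

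With the replicate block 967 genes were called for TORIN1 (704 shared) and 900 for KO (734 shared), and no count moved by over 1.5 times. Of the results for single named genes 129 kept direction and call with the block, 8 lost the call, 1 gained it and 1 changed sign. Of the list results 166 kept theirs, 2 lost it and 5 gained it. Samples with the same number deviated together, with a correlation over 0.1, in 3 of 4 pairs in the TORIN1 set, 1 of 4 in KO, 0 of 5 in end buds and 5 of 60 in glands, so not every pair of any set passed 0.1 and the numbers were not taken to pair the samples. In the TORIN1 set the median was 0.293 for the same letter and -0.150 for different letters, but DMSO C and D correlated better with another letter, so a shared origin stays open there. For the culture set no paired analysis was possible because it is not given in the sources used here whether the numbers in its column names are those of the replicates.

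Egfr from E13 to E18 was 0.00546 in the fit of only these stages. With TORIN1, Erbb3 was 0.0716 without TORIN1 A and DMSO D and 0.0412 in a leave-one-out fit, and Egfr was -0.0604 with the block and -0.13 in a leave-one-out fit. Aqp5 in KO was 0.19 in replicates 3 and 4 alone. None of these was called in the reported fit or in that setting. In KO, Epcam was 0.137 and Col1a1 -0.185 with the tissue balance covariate, 0.0240 and -0.0701 in a leave-one-out fit, and 0.448 and -0.525 in replicates 3 and 4 alone, where both were called, against no call and the other sign in the reported fit. Without TORIN1 A and DMSO D, Aqp5 (-0.83), Egfr (0.29) and Erbb2 (0.21) were called for TORIN1. Of the results for single named genes, 154 kept direction and call with the size factors of DESeq2, without a filter and with the stricter filter, and 116 when each sample was left out in turn, with 34 losing the call. With an estimated correlation 136 list results kept theirs and 58 lost it. Erbb3 in KO was called with the block and with DESeq2 (-0.93).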

Other observations

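The genes below were chosen after their values were seen. The sample E15 C held transcripts of cornified epidermis. Krt1 had 1413 CPM in it and 1.16 to 3.06 in the other E15 samples, Krt10 had 1388 against 5.50 to 11.03, and Lor, the gene of loricrin, had 993 against 0.311 to 2.27.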
